A study of Desulfoluna spongiiphila with 6 samples.

How the data were processed

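The data were raw counts per gene from 6 RNA-seq libraries of Desulfoluna spongiiphila AA1, 3 from cultures given sulfate and 3 from cultures given 2,6-dibromophenol, each at 200 µM and at 12 h. Per the labels' protocols, RNA was extracted with Trizol and a column with a DNase step, depleted of ribosomal RNA and made into libraries with a TruSeq RNA kit (version 2), which does not mark strand. Reads from overlapping or antisense genes can therefore not be told apart, and reads can be shared between near-identical copies. The deposited values are whole-number counts that were not normalized, per the file headers and the values, and totals differed between libraries, from 2616328 to 3324207. DESeq2 is named in the submitters' processing notes without a version. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, and no reference genome was used here, so positions are given only as the order of locus tags.

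Samples were grouped by the titles of the samples. Before any test, libraries were compared in pairs: chi-square divided by its degrees of freedom over gene counts was at least 7.23 in each pair, so no pair differed by sampling noise alone. The 10 most counted genes took 10.3% to 13.3% of a library's counts. A gene with no count in a library of this depth could have been present at up to 3 counts, or 0.90 to 1.15 CPM, which covers counting error only. The table held 5203 rows, of which 13 had no count in any library; each row carried a protein accession and none was a ribosomal or transfer RNA, so the planned fit without such rows was not applicable.

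The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM scaling and the default filterByExpr filter, which left 4784 genes and removed 419. P-values were adjusted by the Benjamini-Hochberg method over tested genes, and an adjusted p under 0.05 was taken as passing. Fold changes are 2,6-dibromophenol over sulfate, and the standard error is the log2 fold change divided by the square root of F. CPM values are counts scaled by TMM library size. TMM factors ran from 0.916 to 1.05. The fit was tested on simulated counts for the same 4784 genes with 200 genes changed, in 5 draws. It recovered 34% of genes changed 1.5-fold, 86.9% changed 2-fold and 98.5% changed 4-fold, and 5.7% of its calls were false. The simulated genes varied independently, with the dispersion of the fit in both groups. The real groups differed in spread and neighbouring genes moved together, so these shares may not carry over to the real data.

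Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry (limma 3.58.1), adjusted by the Benjamini-Hochberg method over the lists with at least 3 measured genes. Before the data were examined, 23 lists, the main design, the alternatives and the rule for naming genes were fixed. The lists were to be matched by product or symbol; the table gives symbols only, so 9 lists matched nothing and 12 in all could not be tested: reductive dehalogenases, their neighbours, membrane electron transfer, aminoacyl-tRNA synthetases, efflux, aromatic compounds, transcription regulators, mobile elements and stable RNA matched nothing, and the lists of lactate oxidation, hydrogenases and iron uptake had 2 genes each. A further 18 lists were drawn up by symbol once the symbols were known and before any fit, and 17 were tested; phosphonate use had 2 measured genes, neither of which passed. Of these 18 lists, the report gives those with a camera call and a few others. By name and with camera adjusted p, the rest were elongation factors and RNA polymerase (0.98), ribosome assembly (0.66), nucleotide synthesis (0.66), glycerol use (0.61), choline and betaine use (0.98), phosphate uptake (0.98), heme and menaquinone synthesis (0.27), molybdenum (0.98), surface sugars (0.99), peptidoglycan and cell division (0.98), protein export (0.98) and DNA recombination and repair (0.66). By fry, 4 of the 17 passed: aminoacyl-tRNA synthetases (0.0093), thiamine synthesis (0.0080), lower glycolysis (0.049) and heme and menaquinone synthesis (0.0084). The median and the mean differed in sign for elongation factors, choline use, molybdenum and peptidoglycan.

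The naming rule took the sulfate reduction subunits, the 12 largest rises and the 12 largest falls among genes that passed, with groups that did not overlap and a mean of at least 50 counts in the higher group, and up to 4 called members of each fixed list or else its most counted member. Since most of the largest changes lie in genes without a name, at most 2 locus tags are named each way. The 12 largest changes with a symbol each way, the same choice for the added lists, the runs of consecutive genes, and genes given as context beside a list or a numbered copy were chosen after values were seen. Runs are at least 3 genes with consecutive locus tags that passed in the same direction.

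Alternatives were DESeq2 size factors, library totals and upper-quartile scaling, no filter beyond 1 count and a filter of 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, glmTreat against a fold of 1.5, leaving out the 10 most counted genes, the replicate number as a block, and leaving out each library in turn.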

Results

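Messenger RNA was measured in cultures of Desulfoluna spongiiphila AA1, an anaerobic marine bacterium that respires sulfate and can also use brominated phenols as electron acceptors. Cells were grown on 30 mM lactate and 20 mM sulfate for 3 days. Then 300 mL of culture was mixed with 300 mL of sulfate-free medium that held 2 mM lactate. Any sulfate left from that culture was carried into both groups, in amounts not measured here. The mixtures were then given either 200 µM sulfate or 200 µM 2,6-dibromophenol, a phenol that carries bromine on both carbons next to the hydroxyl group. Each group held 3 libraries, all from 12 h. Total counts were 2674454, 3324207 and 2918116 in sulfate replicates 1, 2 and 3, and 3168299, 3085650 and 2616328 in 2,6-dibromophenol replicates 1, 2 and 3. The table listed 5203 genes, of which 391 had a gene symbol and 4812 had a locus tag without a name. The labels do not say whether each library came from a separate pre-culture, so p-values measure the spread between these samples, which may be partly technical.

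The comparison asked which transcripts differed between cells given a halogenated electron acceptor and cells given added sulfate. Since carried-over sulfate was not measured, a change of acceptor cannot be told apart from the presence of the added compound. With 2,6-dibromophenol, genes for tryptophan synthesis rose, trpD by 11.0-fold, and a run of 7 adjacent unnamed genes rose by up to 460-fold. Smaller rises included thiF of thiamine synthesis (1.92-fold), the lipoate synthase gene lipA (2.28-fold) and pgk_1 of lower glycolysis (1.99-fold). Genes that fell included cydB, a subunit of the oxygen-reducing cytochrome bd oxidase, by 4.08-fold, and a run of 14 adjacent unnamed genes by up to 14.6-fold. The genes sat, aprA, aprB, dsrA and dsrB, which encode the enzymes of sulfate reduction, were 1.46- to 1.55-fold lower in their fitted values, and none of the 5 passed the test over all genes. Of 4784 genes tested, 383 passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 157 higher and 226 lower with 2,6-dibromophenol, and 205 of them differed at least 2-fold, 63 higher and 142 lower. The excess of falls at 2-fold shrank with some libraries left out, to 58 higher and 68 lower without 2,6-dibromophenol replicate 3 and 55 higher and 83 lower without 2,6-dibromophenol replicate 1. Scaling by library totals alone moved the split to 236 higher and 188 lower, and moved the median log2 fold change of all genes to 0.11.

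The largest rises belonged to genes without a name. BLQ12_RS18825 went from 6.41 ± 1.52 CPM (SD, n = 3) with sulfate to 2922 ± 124 CPM (SD, n = 3) with 2,6-dibromophenol, a log2 fold change of 8.85 (SE 0.22, edgeR Benjamini-Hochberg adjusted p = 3.1e-09). The gene after it in locus order, BLQ12_RS18830, had a log2 fold change of 8.80 (SE 0.26, edgeR Benjamini-Hochberg adjusted p = 9.6e-09), which rests on 2, 1 and 4 counts in the sulfate libraries. They lay in a run of 7 consecutive locus tags that all rose, with a median log2 fold change of 6.99 and a range from 1.28 to 8.85. The share of all counts taken by this run was 0.00375% ± 0.00047 (SD, n = 3) with sulfate and 0.455% ± 0.017 (SD, n = 3) with 2,6-dibromophenol. The genes of the run had between 4 and 206 counts over the sulfate libraries together, so the largest folds are imprecise. All 7 passed the test whichever library was left out. The table does not pair these locus tags with names or products, and reductive dehalogenases, the enzymes that remove halogens in organohalide respiration, were not analysed here by name.

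Tryptophan genes made up the largest named rises. The gene trpD, for anthranilate phosphoribosyltransferase, went from 134 ± 33 CPM to 1477 ± 186 CPM (SD, n = 3 each), a log2 fold change of 3.46 (SE 0.20, edgeR Benjamini-Hochberg adjusted p = 2.4e-06). The gene trpB_1, a copy of the tryptophan synthase beta subunit, rose by 3.41 on the log2 scale (SE 0.23, edgeR Benjamini-Hochberg adjusted p = 5.9e-06). Both lay in a run of 8 consecutive genes that all rose, with log2 fold changes from 0.70 to 3.68, and the run took 0.108% ± 0.030 of counts with sulfate and 1.20% ± 0.14 with 2,6-dibromophenol (SD, n = 3 each). At another locus, trpS_1, a tryptophanyl-tRNA synthetase, rose from 30.3 ± 6.4 CPM to 323 ± 42 CPM (SD, n = 3 each; edgeR Benjamini-Hochberg adjusted p = 1.1e-06). The second copies had log2 fold changes of 0.86 for trpB_2 (SE 0.18, edgeR Benjamini-Hochberg adjusted p = 0.015) and 0.06 for trpS_2 (adjusted p = 0.90), whose sign changed when some libraries were left out. The gene aroA, of the shikimate pathway that leads to the aromatic amino acids, rose by 1.38 (SE 0.22, edgeR Benjamini-Hochberg adjusted p = 0.0044) within a run of 6 genes that all rose. Numbered copies can share reads, so the split between them is uncertain. Without sulfate replicate 3 or any 1 of the 2,6-dibromophenol libraries, trpB_2 missed the threshold (adjusted p from 0.054 to 0.094).

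Further named genes rose, the 10 given next by 0.76 to 1.25 on the log2 scale. In thiamine synthesis, thiS, thiF and thiE_1 rose with log2 fold changes of 1.07 (SE 0.23), 0.94 (SE 0.13) and 0.93 (SE 0.13), while thiL, thiD and thiE_2 did not pass, at 0.06, 0.19 and −0.14. The lipoate synthase gene lipA rose by 1.19 (SE 0.21), and gcvH, for the lipoate-carrying H protein of the glycine cleavage system, rose by 1.25 (SE 0.22). In lower glycolysis, pgk_1 and gap_2, for phosphoglycerate kinase and glyceraldehyde-3-phosphate dehydrogenase, rose by 0.99 (SE 0.16) and 0.98 (SE 0.15), and the other 6 members measured did not pass. Both lay in a single run of 3 genes. The further copies pgk_2, gap_1 and gap_3, among those that did not pass, were at −0.05, 0.33 and 0.03. The menaquinone synthesis gene mqnC rose by 0.86 (SE 0.15), the uracil phosphoribosyltransferase gene upp by 0.76 (SE 0.14) and eutP by 0.89 (SE 0.18). Leaving out single libraries ended some of these calls. The edgeR Benjamini-Hochberg adjusted p for thiS was 0.074 without sulfate replicate 3, 0.063 without 2,6-dibromophenol replicate 1 and 0.081 without 2,6-dibromophenol replicate 3. For eutP it was 0.061 and 0.076 without 2,6-dibromophenol replicates 1 and 3, and for mqnC 0.054 without 2,6-dibromophenol replicate 3.

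Among named genes, 9 fell with 2,6-dibromophenol and 22 rose. The gene cydB went from 1112 ± 489 CPM to 272 ± 65 CPM (SD, n = 3 each), a log2 fold change of −2.03 (SE 0.31, edgeR Benjamini-Hochberg adjusted p = 0.003). The gene cooS_2, for a carbon monoxide dehydrogenase, fell by 1.16 on the log2 scale (SE 0.27), and xth, for an exonuclease, fell by 1.05 (SE 0.20). The branched-chain amino acid synthesis genes ilvD and ilvB_2, adjacent in locus order, fell by 0.80 (SE 0.14) and 0.74 (SE 0.13). The dihydrolipoyl dehydrogenase gene lpdA_2 fell by 0.92 (SE 0.19), asnB_1, for an asparagine synthetase, by 0.78 (SE 0.15) and gcvT, for the T protein of glycine cleavage, by 0.52 (SE 0.14). Other copies did not pass, with ilvB_1 at 0.08 and asnB_2, asnB_3 and asnB_4 at −0.22, −0.41 and −0.0073. With single libraries left out, cydB and ilvD passed in each case. The call for cooS_2 ended without sulfate replicate 3 (edgeR Benjamini-Hochberg adjusted p = 0.086) and without each 2,6-dibromophenol library in turn (0.070 to 0.145). Without 2,6-dibromophenol replicate 3 the adjusted p was 0.064 for xth, 0.063 for lpdA_2, 0.055 for ilvB_2 and 0.070 for asnB_1, and without 2,6-dibromophenol replicate 2 it was 0.050 for ilvB_2 and 0.058 for asnB_1. Of the libraries left out in turn, only sulfate replicate 2 left the call for gcvT in place (adjusted p from 0.13 to 0.19 without the others), and library totals, DESeq2, limma-voom and the replicate number as a block ended it (0.117, 0.102, 0.060 and 0.109).

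Most of the largest falls also lay in runs of unnamed genes. BLQ12_RS22360 went from 4831 ± 1541 CPM to 330 ± 77 CPM (SD, n = 3 each), a log2 fold change of −3.87 (SE 0.29, edgeR Benjamini-Hochberg adjusted p = 1.4e-05), and BLQ12_RS22350 had −3.86 (SE 0.32, edgeR Benjamini-Hochberg adjusted p = 3.3e-05). They belonged to a run of 14 genes that all fell and that took 1.38% ± 0.34 of counts with sulfate and 0.168% ± 0.022 with 2,6-dibromophenol (SD, n = 3 each). All 14 passed whichever library was left out. Runs of 13, 15 and 6 genes fell with median log2 fold changes of −2.02, −1.91 and −1.82. The sulfate libraries differed widely in these runs: the 13 genes averaged 212, 594 and 911 CPM in sulfate replicates 1, 2 and 3, against 115 to 150 CPM in the 2,6-dibromophenol libraries. None of the 13, 15 and 6 genes passed without 2,6-dibromophenol replicate 1, and 1, 1 and 0 passed without 2,6-dibromophenol replicate 3.

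**Figure D1:**
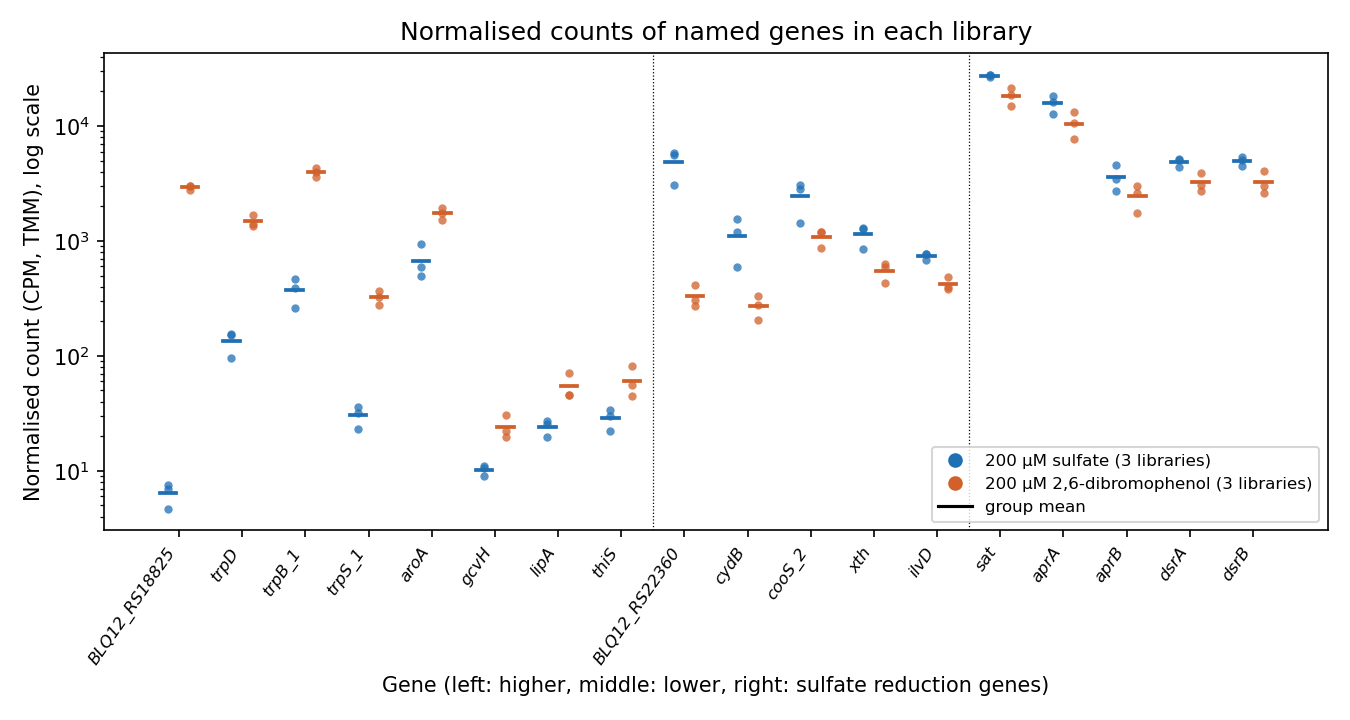
Normalised counts of 18 genes in CPM on a log scale; points are single libraries (3 per group), bars are group means, blue is sulfate and orange is 2,6-dibromophenol. BLQ12_RS18825 lies at 6.41 CPM on average with sulfate and at 2922 CPM with 2,6-dibromophenol, while sat lies at 27430 and 18381 CPM.

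Sulfate reduction was the only fixed gene list past the camera set test. The gene sat, for ATP sulfurylase, was at 27430 ± 784 CPM with sulfate and 18381 ± 3267 CPM with 2,6-dibromophenol (SD, n = 3 each), a log2 fold change of −0.58 (SE 0.23, edgeR Benjamini-Hochberg adjusted p = 0.18). The adenylylsulfate reductase genes aprA and aprB had log2 fold changes of −0.59 (SE 0.25) and −0.55 (SE 0.24), and the dissimilatory sulfite reductase genes dsrA and dsrB had −0.60 (SE 0.18) and −0.63 (SE 0.20), with edgeR Benjamini-Hochberg adjusted p from 0.080 to 0.23. All 5 lay below 0. Over all genes 0 of 5 passed, and 5 of 5 when adjusted over the list alone. The latter holds whenever each unadjusted p is under 0.05, which edgeR gave for 992 of the 4784 genes tested. The list passed camera with the preset correlation of 0.01 (Benjamini-Hochberg adjusted p = 0.040 over 11 lists). It did not pass with an estimated correlation between its members of 0.835 (adjusted p = 0.92 with an estimated correlation) or by fry (adjusted p = 0.14). Together the 5 genes took 5.47% ± 0.73 of counts with sulfate and 3.91% ± 0.74 with 2,6-dibromophenol (SD, n = 3 each). Between aprA and sat in locus order lay a run of 3 unnamed genes that passed and fell. Their median log2 fold change was −0.75 (edgeR Benjamini-Hochberg adjusted p up to 0.027). In this run 0 genes passed without sulfate replicate 3 or without 2,6-dibromophenol replicate 2 or 3, and 2 passed without 2,6-dibromophenol replicate 1. DESeq2 called sat, aprA, dsrA and dsrB lower (adjusted p from 0.0078 to 0.045). The camera call ended without sulfate replicate 2 or 3 (adjusted p = 0.089 and 0.065) and without 2,6-dibromophenol replicate 2 or 3 (0.24 and 0.057). It also ended with a filter of 50 counts (0.063), with the replicate number as a block (0.063) and without the 10 most counted genes, 2 of which belong to the list (0.19).

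The other fixed lists held few calls. Of the 3 carbon monoxide dehydrogenase genes that made up the one-carbon list, cooS_2 fell. The genes cooS_1 and cooS_3 had log2 fold changes of −0.27 and −0.43, and cooS_3 passed without sulfate replicate 2 (edgeR adjusted p = 0.019). All 3 passed when adjusted over the list alone, which follows from unadjusted p under 0.05 for each. That list did not pass camera (adjusted p = 0.18), except without sulfate replicate 2, when it was the only fixed list that did. None of the 7 ATP synthase genes passed; 6 lay below 0, with atpD at −0.41 (SE 0.16; adjusted p = 0.013 by edgeR without sulfate replicate 2), and the list passed fry (adjusted p = 0.036) but not camera (adjusted p = 0.28). In nitrogen fixation and ammonium assimilation 0 of 7 passed, with nifJ_1, for a pyruvate:ferredoxin (flavodoxin) oxidoreductase, at −0.66 (SE 0.20, edgeR Benjamini-Hochberg adjusted p = 0.079); it passed by DESeq2 (0.0042) and without sulfate replicate 2 (0.027). No gene passed among 9 genes of corrinoid synthesis and uptake (median log2 fold change 0.06) or 9 ribosomal proteins (0.03). The same held for 11 chaperones and stress proteases (0.03), 3 genes of fatty acid synthesis (0.0058) and 3 of oxygen defence and thiol proteins (−0.01). It also held for the 23 genes of the flagella and chemotaxis list (−0.06), each with an flh, fli or flg symbol. Of these, flhA passed without sulfate replicate 2 (edgeR adjusted p = 0.034). In the organic sulfur list (0.09) none of the 4 genes passed, which were cysC_1, cysC_2, cysC_3 and cysK. Chemotaxis, sulfatase and sulfonate genes were thus not measured by name. Lists of lactate oxidation (nifJ_1 and nifJ_2), hydrogenases and formate dehydrogenases (hydF and hypB), and iron uptake (feoB_1 and feoB_2) each had 2 measured genes. None of these passed, and the lists were too small for the set test. No other gene of these lists was measured by name. Adjusted over the list alone, nifJ_1 was lower in the lactate oxidation list, hydF (at −0.43) in the hydrogenase list and accC (at −1.17) in fatty acid synthesis. In the other lists of this paragraph 0 genes passed in this way, apart from the one-carbon list. For ribosomal proteins and fatty acid synthesis the mean (−0.00070 and −0.344) and the test were below 0 and the median above it.

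**Figure D2:**
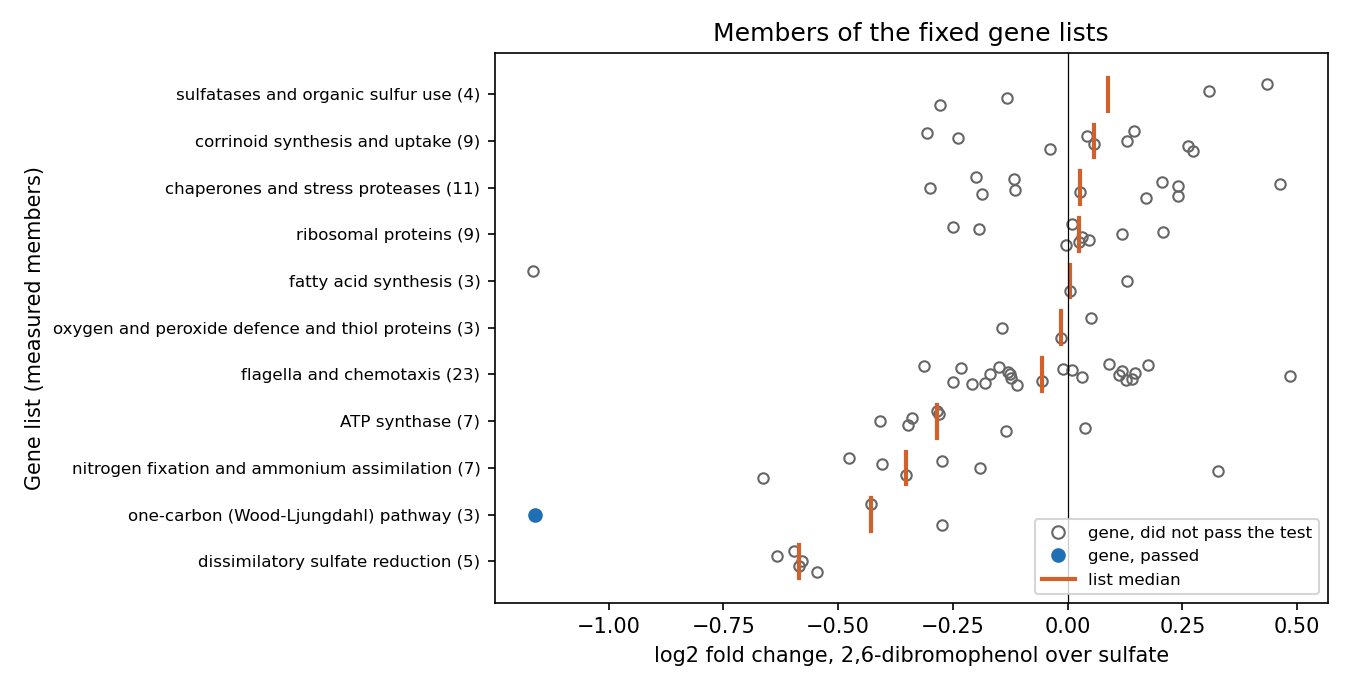
Log2 fold changes (2,6-dibromophenol over sulfate) of the members of the 11 fixed gene lists that were tested; open circles did not pass the test over all genes, filled circles did, and orange bars are list medians. The 5 sulfate reduction genes lie between −0.63 and −0.55, and cooS_2 is the filled circle.

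Among lists drawn up from the symbols in the table before any fit, 2 of 17 passed camera. Aminoacyl-tRNA synthetases passed upward (adjusted p = 9.3e-05) but not with an estimated correlation between members (adjusted p = 0.38). Of its 4 genes 1 was called, trpS_1 at 3.40, which is among the tryptophan genes given above. The others were trpS_2 at 0.06, and lysS and glyQ at 0.35 and 0.38 (edgeR adjusted p = 0.040 and 0.036 without sulfate replicate 2). The list mean was 1.05 and its median 0.366, so the mean rests largely on trpS_1. Thiamine synthesis passed upward (adjusted p = 0.025), with 3 of 6 genes called, but not with an estimated correlation (adjusted p = 0.38). The thiamine call also ended without sulfate replicate 2 (adjusted p = 0.11), with a filter of 50 counts (0.053) and with the replicate number as a block (0.051). In amino acid synthesis 4 of 28 genes rose (trpD, trpB_1, trpB_2 and aroA) and 3 fell (ilvD, ilvB_2 and asnB_1), and the list did not pass (adjusted p = 0.27). Lower glycolysis missed the threshold (adjusted p = 0.073) but passed with library totals, without sulfate replicate 1 and by fry (adjusted p = 0.049), as heme and menaquinone synthesis did by fry (0.0084). None of the 4 citric acid cycle genes passed, with sdhA at −0.49 (SE 0.13) the nearest (edgeR Benjamini-Hochberg adjusted p = 0.052); it passed with the upper quartile, a filter of 50 counts, DESeq2, and without sulfate replicate 2 (0.041, 0.040, 0.044 and 0.0058).

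Libraries separated by group. Pearson correlations of log2 CPM across genes were 0.975 to 0.985 within sulfate, 0.990 to 0.991 within 2,6-dibromophenol and 0.951 to 0.966 between groups, where genes are not independent replicates. The first principal component held 59.3% of the variance and parted the groups, and the second held 18.7% and set sulfate replicate 2 apart from the other 5 libraries. Sulfate libraries varied more, with a median SD of log2 CPM of 0.226 against 0.142. The 3 values of each group did not overlap for 26.8% of tested genes, against 10% by chance. The count of 383 genes became 719 without sulfate replicate 2, 246 without sulfate replicate 3, and 177, 209 and 165 without 2,6-dibromophenol replicates 1, 2 and 3.

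**Figure D3:**
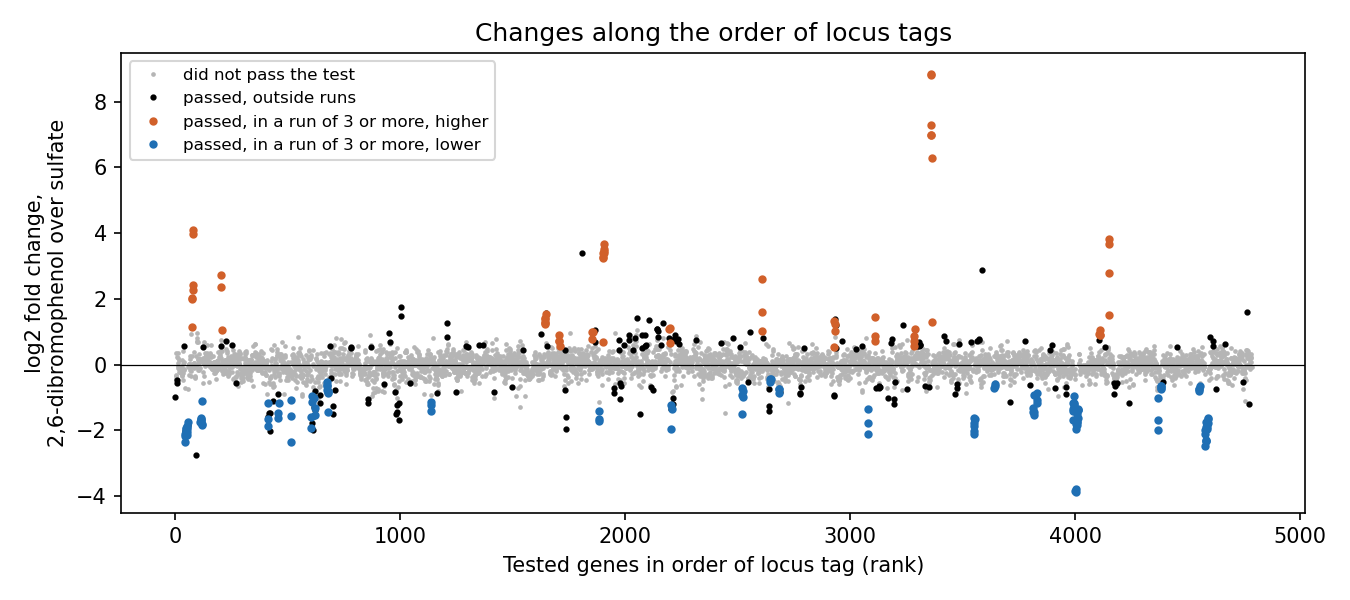
Log2 fold changes (2,6-dibromophenol over sulfate) of the 4784 tested genes in order of locus tag; coloured points are genes that passed the test in runs of 3 or more consecutive locus tags with the same direction, orange higher and blue lower, and black points passed outside runs. The highest run reaches 8.85 and the lowest −3.87.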

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

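The tests of genes 2 places apart, of uncalled genes, of the added lists, of runs under each alternative and, for the sulfate list, of the upper quartile, the stricter filter and the fit without the most counted genes were chosen after seeing the data; the other alternatives were planned. The count of 383 genes stayed within 1.5 times under the scalings, filters, tools and the fit without the 10 most counted genes (344 to 424 genes), and calls shared with the reported ones kept their direction in each alternative. Leaving out 1 library gave 165 to 719 genes, with 73 to 319 higher and 88 to 400 lower, and 126 to 234 at least 2-fold (54 to 73 higher and 68 to 161 lower); the highest counts came without sulfate replicate 2, when 375 of the 383 genes were called again, and a fit on 5 libraries has fewer degrees of freedom. Runs of called genes, 40 in the main fit, numbered 33 to 46 under the other alternatives and 15 to 65 with a library left out. Library totals alone called 236 genes higher. Testing against a fold of 1.5 called 122 genes, counted at any size of change and not as a part of the 205 genes at least 2-fold. That test asks for more than a difference from 0. Of 23 fixed lists, 0 passed with an estimated correlation, and 0 or 1 with a library left out. The labels do not say whether the replicate number pairs the samples, and the values cannot decide it, since correlations were weak either way. Same-numbered libraries deviated from their group means with correlations of 0.06, −0.18 and −0.16, and differently numbered ones with −0.072 to 0.2. Of the 6 libraries, 4 correlated best with a library of another number. As a block the replicate number gave 299 genes, 104 of them higher, and 0 fixed lists and 1 added list, the aminoacyl-tRNA synthetases. Of 35 called genes named in the text, 17 kept their call in all 15 alternatives other than the test against a fold of 1.5. Calls of single genes were not compared under that test. Of the 65 single genes checked in each alternative, 8 changed sign. None of these passed in those settings (smallest adjusted p 0.652), and the cause was not tested. Other genes were not checked for sign changes. Medians of some lists also changed sign with a library left out, such as ribosomal proteins (−0.0702 to 0.0757), chaperones (−0.0741 to 0.0828), flagella (−0.121 to 0.0623) and organic sulfur use (−0.0477 to 0.166). By library totals cobA was at 0.075, rimM at 0.0034 and pstC at 0.092. The fatty acid gene fabG, at 0.0058, was at −0.0017 with DESeq2 size factors, −0.015 with the upper quartile, −0.0034 with the stricter filter, −0.0017 with DESeq2 and −0.0011 without the 10 most counted genes. With a library left out, cobA ran from −0.14 to 0.045, cysK from −0.37 to 0.039, fabG from −0.095 to 0.19, pstC from −0.35 to 0.17, secD from −0.0081 to 0.088, trpS_2 from −0.059 to 0.23 and thiL from −0.10 to 0.18. In simulated data with 3 libraries per group 34% of 1.5-fold changes were recovered, so small changes can be missed.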

Other observations

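Of the tests below, those on single libraries, on tryptophan genes, on genes 2 places apart, on runs with a library left out and on loci were chosen after the results were seen. Named genes in a short stretch of locus tags moved in opposite directions; the stretch was picked after values were seen and has no set test. Of its genes, lpdA_2 had a log2 fold change of −0.92 (SE 0.19) and ald of −0.97 (SE 0.23), while gcvH and lipA, a few genes further on, had 1.25 (SE 0.22) and 1.19 (SE 0.21). Without 2,6-dibromophenol replicate 3 the edgeR Benjamini-Hochberg adjusted p was 0.063 for lpdA_2 and 0.13 for ald. The call for ald also ended without sulfate replicate 3 (0.087) and without 2,6-dibromophenol replicates 1 and 2 (0.074 and 0.122), while gcvH and lipA passed whichever library was left out. Named genes with smaller rises were brnQ (0.79, SE 0.19), glpA (0.64, SE 0.16), yedF (0.60, SE 0.16), ygbF_2 (0.59, SE 0.13), typA (0.58, SE 0.15), alr (0.54, SE 0.13) and parE (0.44, SE 0.12), each of which missed the threshold without sulfate replicate 3, without 2,6-dibromophenol replicate 1 and without 2,6-dibromophenol replicate 3 (edgeR Benjamini-Hochberg adjusted p from 0.060 to 0.218). The replicate block ended these calls too except that of brnQ (adjusted p from 0.057 to 0.139), and other libraries left out or other settings ended some of them.

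Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes, the real one, with 383 genes and 205 at least 2-fold (1 of 10 for both counts). The highest of the other splits called 0 genes by edgeR, with 49 to 470 genes at an unadjusted p under 0.05. These splits are too few for a share under 0.05.

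The sulfate reduction genes, 0 of 5 of which passed over all genes, had a median log2 fold change of −0.59 in their fitted values. A single library does not account for it, since the median stayed between −0.75 and −0.46 with each library left out (SD 0.11). A trend of fold change with abundance stays open. The median lay at percentile 1.52 of 10000 random lists of 5 genes matched on abundance, under the bound of 5 set beforehand. That bound was wrong for genes that move together (estimated correlation 0.835) and lie at 2 loci. With 1 matched gene drawn per locus the percentile was 9.3, and 68.2% of the 107 matched genes lay below 0. The matched genes had a median of −0.125 (interquartile range −0.353 to 0.0545), smaller in size than that of the 5 genes. A response to the added compound, which the design names, also stays open.

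Of the 5 genes with a trp symbol, picked after values were seen and without a set test, 4 passed upward (trpD, trpB_1, trpB_2 and trpS_1) and trpS_2 did not (log2 fold change 0.06, edgeR Benjamini-Hochberg adjusted p = 0.90). Reads shared between the numbered copies of trpB and trpS do not account for the rise, since moving reads between copies leaves their sum as it was. The summed CPM of the copies rose from 1749 ± 251 to 6454 ± 522 for trpB (log2 difference 1.89, SE 0.14) and from 110 ± 22.5 to 406 ± 51.7 for trpS (1.90, SE 0.20; SD, n = 3 each). A rise of amino acid synthesis genes in general does not account for it either, since the 25 genes of that list other than trp genes had a median of −0.0033 (spread 0.082), with 1 higher and 3 lower. A response of the tryptophan genes to the added compound stays open as a hypothesis, and no test here bears on how it would arise. Whether it is specific to tryptophan was not tested, and aroA of the shikimate pathway also rose (log2 fold change 1.38).

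Genes next to each other changed together. Across 4388 pairs of adjacent genes the Pearson correlation of log2 fold changes was 0.724 (Spearman 0.479), above each of 10000 shuffles of gene order (permutation p = 1e-04, the smallest they can give), and 0.362 among genes that did not pass. Runs of 3 or more called genes numbered 40 and held 51.2% of called genes, against a mean of 0.544 runs in shuffles. The shuffles test gene order only. Neighbours that share their spread between replicates would also exceed them, and the correlation was not computed for other splits of the libraries. The number of runs ranged from 15 without 2,6-dibromophenol replicate 3 to 65 without sulfate replicate 2, and they held 43.1% to 55.1% of the genes called with a library left out. Reads of one gene counted in the next do not alone account for the correlation, since genes 2 places apart still correlated at 0.57 and genes 5 apart at 0.264. Genes transcribed together in operons may account for the pattern; transcript boundaries were not analysed here, and genes are not independent replicates.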
